A study of Drosophila melanogaster with 2 samples.

How the data were processed

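Small RNA of 19 to 28 nt was size-selected from total ovarian RNA of Drosophila melanogaster and sequenced, per the labels' protocols. The flies were 3 to 5 days old and had been kept at 25 °C. There were 2 libraries, 1 from flies heterozygous and 1 from flies homozygous for the mutation z3-5967. The strain labels spell the mutated gene GC5508, and the sample titles and the design text spell it CG5508, the name used here. The deposited counts are whole numbers of reads for each distinct sequence in 1 library, per the file headers, with no normalization. Beside each count the deposited tables give the number of genome positions the sequence maps to and 1 annotation class, per the file headers: miRNA, gene, repeat, synthetic, non-genomic or none. The genome build was dm3, per the submitters' processing notes. The aligner, the mismatches it allowed and the order in which classes were given priority are not given in the sources used here.

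The tables pair no sequence with a position, strand, gene, transposon family or miRNA name. No genome sequence was used here. The planned ratios for follicle-cell, intermediate and germline transposon families, the count of families lower by at least 2-fold, the flamenco and 42AB clusters and the genic piRNAs of traffic jam and brat were therefore not run. Segments put together from the reads took the place of families. The design, the miRNA lists and the rule for named miRNAs were fixed before the data were examined. The segments, the structural RNA filter and all values that rest on them were chosen after seeing the data.

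The repeat class held fragments of ribosomal and transfer RNA as well as transposon-derived reads. Mapped reads outside the miRNA and synthetic classes, pooled over both libraries, were put together through shared 19-nt words seen in at least 20 reads. This gave 5938 segments of at least 30 nt, and a read could be placed on either strand of a segment. A segment was treated as structural RNA when at least 99% of its 23 to 28 nt reads lay on 1 strand and under 50% of its distinct 23 to 28 nt sequences began with U, and 775 segments met this rule. Hand-entered stretches of 2S, 5S, 5.8S and 18S rRNA and of tRNA-Asp each fell in 1 structural segment. piRNA-sized reads were mapped reads of 23 to 28 nt in the repeat, gene or unannotated class outside structural segments.

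The 1801 repeat segments with at least 100 piRNA-sized reads over both libraries held 45.1% of the heterozygous and 43.1% of the homozygous piRNA-sized repeat reads. Their median length was 38 nt and the longest had 184 nt, so a segment is a stretch of an element and not a whole family. A segment was called read from 1 strand when at least 95% of its reads lay on 1 strand, and read from both strands when under 80% did. A library with fewer than 3 reads in a segment was set to 3 reads for medians, which applied to 126 segments. Pairs of 5' ends on opposite strands of a segment were counted at overlaps of 1 to 20 nt, each pair of positions adding the smaller of its read numbers.

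miRNA reads were collapsed over isoforms that shared a 15-nt core with the most abundant (leading) sequence and began at most 4 nt before or 2 nt after it. Members of a family that share such a core, as in the miR-2 family, were therefore counted together. Isoforms of 1 RNA were compared only where they matched base for base apart from their ends. Names come from exact matches to a 15-nt stretch of each of 45 mature sequences entered by hand from textbook knowledge, and all 45 were found. The planned miR-2498, miR-991 and miR-992 were not entered and are not analysed here. Named miRNAs were all members of the fixed lists and, among those with at least 1000 reads, the 6 lowest and 6 highest log2 ratios and the 4 most abundant in the heterozygote. Sequences without a matched name are given by their leading read. Strands of 1 hairpin were paired as reciprocal best duplexes of at most -20 kcal/mol with 3' overhangs of 0 to 4 nt, with RNAduplex of ViennaRNA 2.7.2. Homologous miRNAs share much sequence, so a pairing can be wrong; miR-9c with miR-79 is a doubtful case.

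The main unit was reads per 1000000 miRNA reads of the same library, and ratios are log2 of homozygous over heterozygous. With 1 library per genotype no test between genotypes is possible, and a difference has no replicate check. Intervals are exact 95% binomial intervals (Clopper-Pearson for shares, conditional binomial for ratios, order statistics for medians). Reads carry no molecular identifiers, so the intervals of shares and ratios cover counting error only. Those of medians reflect the spread over segments, pairs or isoforms, which they treat as independent. Medians of lists were placed among 10000 random lists of the same size matched on abundance, as a description of these libraries. A count of 0 would allow a share of up to 3.07e-05% in the heterozygous and 1.88e-05% in the homozygous library. Alternatives changed the read length, the unit, the reads counted and the filters one at a time. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

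The steps were tested on simulated data. From 150 simulated piRNA sources and 50 simulated structural sources, 100% of the structural segments and 0.389% of the piRNA segments were called structural. Every simulated piRNA source had reads on both strands that mostly began with U, and structural sources had none on the other strand. Segments near the limits of the rule were therefore not simulated, and their error rate is unknown. A planted 10-nt share of 30% was recovered as 30%. Of 1801 segments with simulated counts, 100 were lowered and 100 raised by 4-fold, and 100% of each were called at the 2-fold limit, with 0% of the unchanged segments. These counts had Poisson error only, at equal depth in both libraries. Other differences between libraries were not simulated, so the rate of false calls in the real comparison is unknown.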

Results

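The study compared small RNAs in ovaries of flies heterozygous and homozygous for the mutation z3-5967 of CG5508, with 1 library per genotype. CG5508 (symbol mino) encodes Minotaur, a homologue of glycerol-3-phosphate acyltransferases, the enzymes that begin phospholipid synthesis. The series title sets the question, which is the need for Minotaur in primary piRNA biogenesis. Primary piRNAs are cut from long single-stranded precursors and guide Piwi proteins against transposons, and in germ cells they also feed the ping-pong cycle of Aubergine and Ago3. The heterozygous library held 9784757 reads of 3236022 distinct sequences, and the homozygous library 15927785 reads of 2414224 distinct sequences. miRNAs, which are made without piRNA factors, accounted for 2037995 and 2545676 reads. Reads without a match to the genome took 31.3% of the heterozygous and 14.3% of the homozygous library. Around the 10 most abundant heterozygous miRNA sequences, unmapped reads with 1 substitution came to a median of 27.1% of the miRNA's reads in the heterozygous and 6.45% in the homozygous library. Short RNAs do not measure the level of the mutated gene, so the genotypes rest on the labels. No value has a replicate.

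The first comparison concerned the piRNA pool as a whole. Per miRNA read the heterozygous ovary had 1.39 piRNA-sized reads and the homozygous ovary 0.488, which is 2.85-fold lower (log2 -1.51, 95% interval -1.512 to -1.505). Repeat-derived piRNA-sized reads were 2.56-fold lower (log2 -1.35), gene-derived reads 3.27-fold lower (log2 -1.71) and unannotated reads 6.10-fold lower (log2 -2.61). piRNA-sized reads that begin with U, the typical first base of Piwi-bound and Aubergine-bound piRNAs, were 3.80-fold lower. The share beginning with U was 78.1% in the heterozygote and 58.4% in the homozygote. In the gene class the U share was 80.7% and 60.3%, in the repeat class 76.0% and 57.2%, and in the unannotated class 80.6% and 68.9%.

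Repeat reads of 25 nt numbered 210417 per 1000000 miRNA reads in the heterozygote and 61944 in the homozygote, and gene reads of 25 nt 158382 and 35979. In both classes 25 nt was the most frequent length in the heterozygote. The log2 ratio went from 1.78 at 21 nt to -1.76 at 25 nt in the repeat class and from 1.94 to -2.14 in the gene class. miRNA reads also had lower ratios at greater lengths, from 0.61 at 21 nt to -0.64 at 23 nt and -2.0 at 25 nt, where they are few. Reads on structural segments had no steady fall with length. Their ratio was 2.47 at 19 nt, 3.10 at 21 nt, 2.15 at 25 nt and 3.19 at 27 nt. Within single miRNAs, 166 isoforms shorter at the 3' end than the leading sequence had a log2 ratio higher by a median of 0.42 (interval 0.15 to 0.51), and 55 longer ones differed by a median of 0.02 (interval -0.27 to 0.32). These 221 isoforms come from 72 miRNAs, and those of 1 miRNA share a leading sequence. The intervals treat them as independent and are likely too narrow. Gene-derived piRNA-sized reads with several genome positions were 4.10-fold lower, while those with 1 position were 1.51-fold lower. The latter began with U in 74.7% of heterozygous and 28.1% of homozygous reads, and among those beginning with U the difference was 4.01-fold.

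Segments called structural went the other way. They took 8.59% of heterozygous and 39.9% of homozygous reads, a 6.05-fold higher level per miRNA read in the homozygote. Only those with the hand-entered rRNA and tRNA stretches were identified, and the largest of these, 2S rRNA, held 1.70% and 4.85% of reads. The others rest on the strand and U-share rule alone. Had reads on structural segments been kept among piRNA-sized reads, the log2 ratio of the pool to miRNA would have been 0.13 instead of -1.51. Mapped reads of 21 nt outside miRNAs and structural segments were 3.59-fold higher in the homozygote. With those 21-nt reads as the unit, the piRNA log2 ratio was -3.35, and with miRNA reads less miR-989 as the unit it was -1.09.

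**Figure D1:**
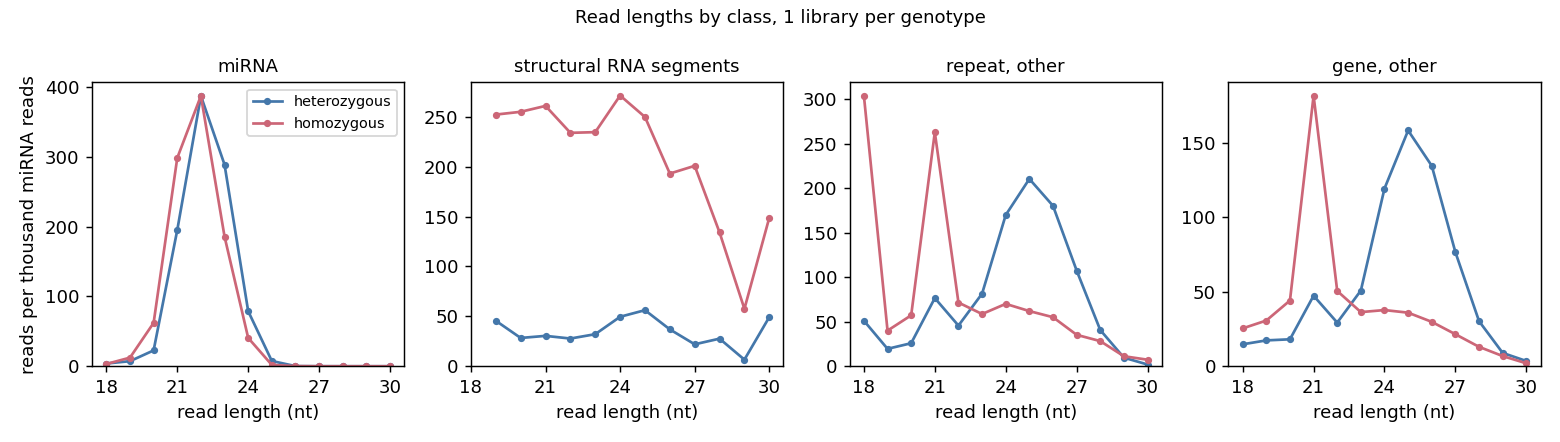
Reads per 1000 miRNA reads (vertical axis) at each read length in nt (horizontal axis) for miRNAs, structural RNA segments, and repeat and gene reads outside those segments; lines are the single heterozygous and homozygous libraries. The 25-nt peak of the heterozygote, 210417 repeat reads per 1000000 miRNA reads, is at 61944 in the homozygote, which peaks at 21 nt and, in the repeat class, also at 18 nt.

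The second comparison took repeat-derived piRNAs apart by segment. Of 1801 repeat segments, 1322 (73.4%) were lower by at least 2-fold in the homozygote, 148 (8.22%) were higher by at least 2-fold, and 331 lay between. The median log2 ratio was -2.94 (95% interval -3.15 to -2.73), and the ratio of the summed reads was -1.42, so abundant segments differed less than the median segment. Among the 243 segments with at least 1000 reads, 148 were lower and 22 higher. Segments whose sequences typically map to 1 genome position had a median over 200 of -4.99 (interval -5.19 to -4.65), with 184 lower and 5 higher, and their summed reads a ratio of -2.82. Over all repeat piRNA-sized reads, placed on segments or not, the log2 ratio was -1.42 for reads with 1 position and -1.34 for those with several. Reads on segments called structural were 6.05-fold higher in the same homozygous library.

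Piwi-bound piRNAs of follicle cells come mostly from 1 strand of their source locus, whereas germline clusters are read from both strands. Segments are short stretches with a median of 38 nt and no known locus. Their split by strand therefore does not tell the strands of the source locus or the cell type. The 1165 segments read from 1 strand had a median log2 ratio of -3.26 (interval -3.47 to -3.00), below all 10000 random lists matched on abundance. For the 181 segments read from both strands the median was -2.47 (interval -3.01 to -2.0), at percentile 96.2 of such lists. Among segments read from 1 strand 867 were lower and 110 higher, and among those read from both strands 131 were lower and 4 higher. The ratios of summed reads were close, at -1.45 and -1.31. The structural RNA rule removes only segments that are read from 1 strand and have a low U share, and homozygous reads had the lower U share. With structural segments kept the medians were -2.55 and -2.47. With a U share of at least 50% asked of every segment they were -3.42 (interval -3.73 to -3.18, 974 segments) and -2.23 (interval -3.37 to -1.52, 81 segments). The intervals overlapped in the main setting, slightly, and in this one. At a minimum of 1000 reads the medians were -1.76 and -0.72, and with distinct sequences counted once they were -1.53 and -1.45.

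The files do not pair segments with element names, so only the extremes among segments with at least 1000 reads are given, by their leading read. Some segments with fewer reads had ratios further from 0. TTGAAGTCACCGGCTGCTATAAAGC led the lowest of these abundant segments, with 1125 heterozygous and 10 homozygous reads in the segment (log2 -7.13, interval -8.20 to -6.25). TGCCTGTCGTACTTTGCTTGGGTACA led the next of them, with 1138 and 12 reads (log2 -6.89, interval -7.85 to -6.08). TTTTGTGATGAAATCGTTAGATAG led the highest, with 18 and 1319 reads (log2 5.87, interval 5.21 to 6.63). ATTTAAGATGATTCGGCGATCTGATGG followed with 17 and 1180 reads (log2 5.8, interval 5.11 to 6.58). At least 99% of the reads of each of these segments lay on 1 strand.

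**Figure D2:**
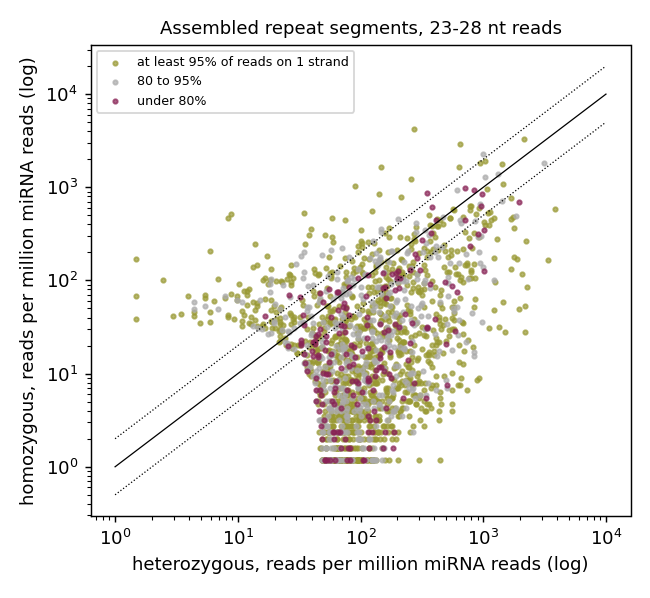
Each point is 1 of 1801 repeat segments, with piRNA-sized reads per 1000000 miRNA reads in the heterozygous (horizontal, log scale) and homozygous (vertical, log scale) library; colours give the share of reads on 1 strand, the solid line equality and the dotted lines 2-fold. Libraries with fewer than 3 reads are drawn at 3 reads, and 1322 points lie at or below the lower dotted line.

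The third comparison concerned ping-pong amplification, in which piRNAs of opposite strands overlap by 10 nt and the partner of a piRNA beginning with U carries A at position 10. The share of opposite-strand pairs overlapping by 10 nt was 8.53% in the heterozygote (interval 8.38% to 8.68%, z 1.71) and 20.7% in the homozygote (interval 20.3% to 21.02%, z 14.5). In the heterozygote the shares rose almost steadily with the overlap to 8.71% at 20 nt, which lowers z. There 10 nt was still a local peak, against 3.86% at 9 nt and 4.68% at 11 nt. In the homozygote the next highest share was 5.59%. Over segments read from both strands the 10-nt share was 9.57% and 23.1%, and over segments read from 1 strand 5.71% and 13.3%. With distinct sequences counted once each the shares were 5.28% and 7.33%. Counted above the mean of the overlaps on either side of 10 nt, there were 2891 pairs per 1000000 miRNA reads in the heterozygote and 3381 in the homozygote (log2 0.23), while reads on the same segments had a log2 ratio of -1.42. Repeat-derived piRNA-sized reads carried A at position 10 in 32.1% of heterozygous and 37.1% of homozygous reads. Among repeat reads that do not begin with U, where ping-pong partners would be sought, the order was the other way, at 44.6% and 39.1%. In the gene class the share over all reads was 27.5% and 35.4%, over reads not beginning with U 32.8% and 32.4%, over reads with 1 genome position 28.0% and 24.1%, and over reads with several positions 27.4% and 40.8%. Gene reads with several positions that do not begin with U carried A at position 10 in 33.8% and 45.5%, and unannotated reads that do not begin with U in 36.7% and 44.4%.

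**Figure D3:**
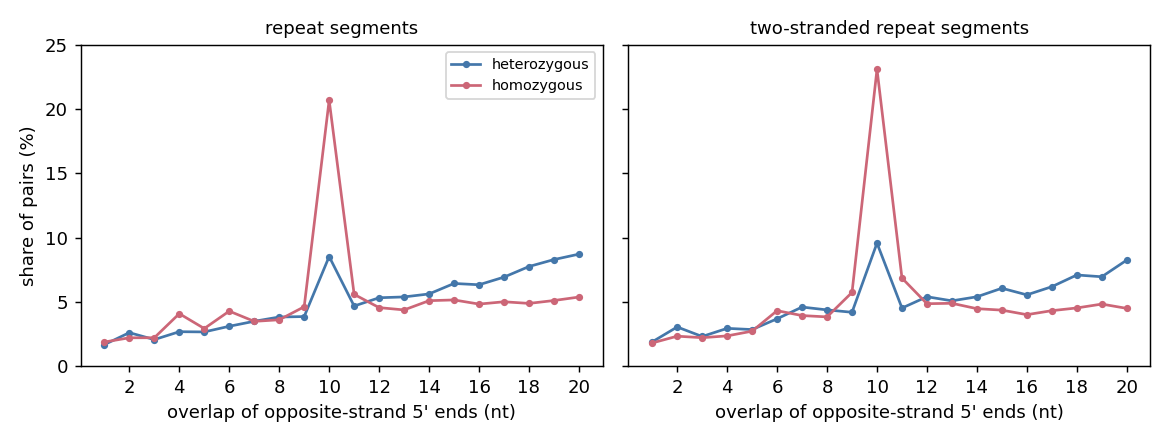
Share of opposite-strand 5' end pairs in percent (vertical axis) at each overlap in nt (horizontal axis), over all repeat segments and over segments read from both strands; lines are the single heterozygous and homozygous libraries. The 10-nt share is 8.53% and 20.7% over all segments, and 9.57% and 23.1% over segments read from both strands.

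The miRNA profiles served to compare the cells in both samples, and they differed widely. Of 128 miRNAs with at least 100 reads, 54 were higher and 24 lower by at least 2-fold per 1000000 miRNA reads in the homozygote, and 50 lay within 2-fold. The median log2 ratio was 0.60. With that median set to 0, 37 were higher and 36 lower, and per 1000000 reads of the file 40 were higher and 31 lower. Ratios below are per 1000000 miRNA reads, so a miRNA at 0.60 moved with the median. Both strands of 1 hairpin, where they could be paired, differed by a median of 1.61 on the log2 scale over 19 pairs.

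Markers of late follicle cells did not move together. miR-989 made up 0.901% of heterozygous and 26.0% of homozygous miRNA reads (log2 4.85), miR-318 had a log2 ratio of -0.42 and miR-994 one of -1.65. The list median, that of miR-318, was close to 0 (-0.000285) with miR-989 left out of the unit. At -0.42 it stood at percentile 26.8 of random lists. The let-7 complex, hormone-dependent miRNAs from 1 transcript, was also divided, with miR-100 at 5.33, miR-125 at 4.98 and let-7 at -0.78. Its median of 4.98 stood at percentile 99.3. The miR-309 cluster, known from the zygotic clearance of maternal mRNA in the embryo, was low in both libraries and far higher in the homozygote: 4 of its 6 members reached 100 reads and all 4 were higher. miR-3 had 12 and 1382 reads (log2 6.53), miR-5 14 and 1207 (log2 6.11), miR-286 4 and 565 (log2 6.82) and miR-6 25 and 208 (log2 2.74). miR-4 had 2 and 57 reads and miR-309 1 and 40.

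Per 1000000 miRNA reads the 4 measured members of the miR-310 cluster lay within 2-fold, with a median log2 ratio of 0.04. Their values were 0.34 for miR-310, 0.46 for miR-312, -0.25 for miR-311 and -0.85 for miR-313. The first 2 had negative signs with the median miRNA set to 0 (-0.26 and -0.13), miR-310 also per 1000000 reads of the file (-0.04), and miR-311 had a positive sign without miR-989 in the unit (0.17). miR-313 left the 2-fold range with the median set to 0 (-1.45) and per 1000000 reads of the file (-1.23). Bantam, a growth-promoting miRNA, was at 1.35, and miR-184, needed for egg production, was at 0.16, at -0.43 with the median set to 0 and at -0.22 per 1000000 reads of the file. miR-8 made up 18.5% of heterozygous and 7.34% of homozygous miRNA reads (log2 -1.33). Within pairs made from 1 transcript, miR-275 was at 1.36 and miR-305 at -3.93, and miR-996 was at 2.81 and miR-279 at -0.60. miR-34 was at 1.30, miR-7 at 1.29 and miR-9a at 1.41.

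Markers of other tissues were sparse or divided. Of the muscle miRNAs, miR-1 had 17436 and 17794 reads (log2 -0.29, and 0.13 without miR-989 in the unit), whereas miR-133 had 47 and 890 (log2 3.92). The neuronal miR-124 had 12 and 15 reads. The lowest ratios among miRNAs with at least 1000 reads were those of miR-306 (log2 -4.96), CACAGTTGCTGTTTCTTTTAGAT (-4.90), miR-12 (-4.66), miR-305 (-3.93), miR-14 (-3.34) and CAATACAACTTCAGTGCAAGCT (-3.11). The highest were those of miR-3, miR-5, miR-100, miR-125, miR-989 and miR-278 (log2 4.64). Among the 4 most abundant in the heterozygote, miR-2, counted with family members that share its core sequence, took 19.6% of heterozygous and 4.89% of homozygous miRNA reads (log2 -2.0), miR-306 8.41% and 0.270%, and miR-11 was at 5.53% and 8.45% (log2 0.61). miR-8 was the remaining one.

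**Figure D4:**
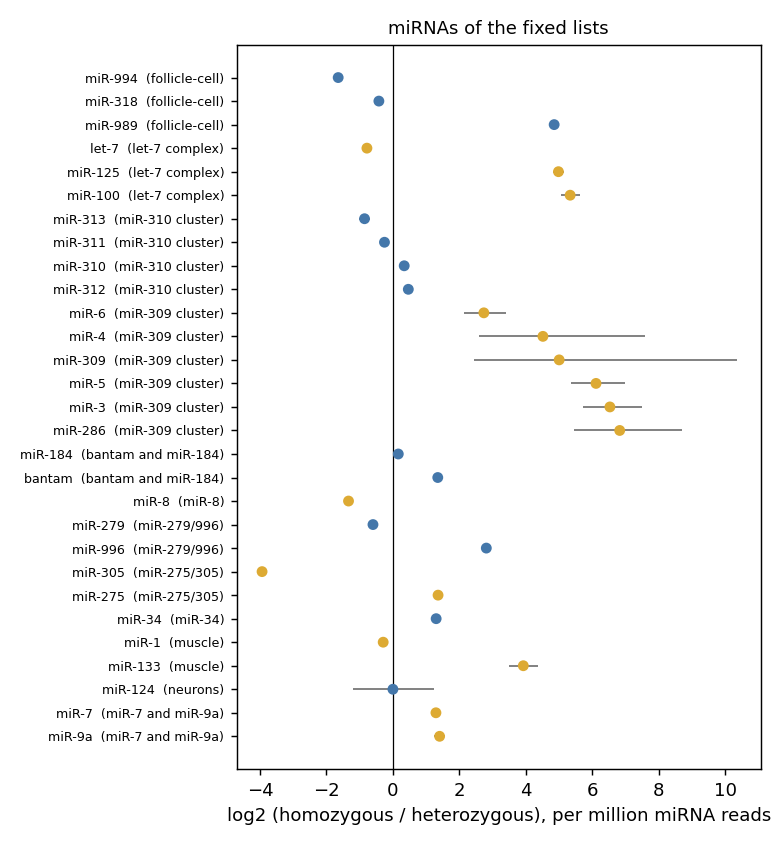
Log2 ratio of homozygous over heterozygous reads per 1000000 miRNA reads (horizontal axis) for the miRNAs of the fixed lists (vertical axis, list in brackets); points are single library ratios and bars exact 95% binomial intervals, hidden by the point where narrow. Members of 1 list lie far apart, as with miR-989 at 4.85 and miR-994 at -1.65.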

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

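The values here lie outside the main comparisons of the report, except for the miRNA and overlap patterns weighed after them. The tests of hairpin abundance alone, of RNA from another organism and of partners at equal read numbers were chosen only after their results had been seen.

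Unmapped reads of 23 to 28 nt made up 19.6% of the heterozygous and 5.73% of the homozygous library, and the main comparisons left them out. The heterozygous ones resembled piRNAs, with 72.3% beginning with U, which argues against RNA of an organism without piRNAs, and 56.2% were 1 substitution away from a mapped sequence. Only 22.4% of those substitutions lay in the last 5 positions, where an even spread would put 19.99%, which argues against decay of quality at the 3' end. Strain variants stay open: 13% of the 1-substitution reads were at least as abundant as their mapped neighbour, but a variant fixed in the strain would leave no such neighbour. Substitution errors anywhere in the read may account for many of them: neighbours of the 10 most abundant heterozygous miRNA sequences had a median of 27.1% of those miRNAs' reads, against 6.45% in the homozygous library, though the origin of the remaining unmapped reads stays open and the genotypes could not be set apart from the libraries.

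Synthetic marker sequences took 0.872% of the heterozygous and 0.203% of the homozygous library. The sequence CGTACGGTTTAAACTTCGA gave 75110 and 20984 of these reads. Reads annotated as non-genomic took 0.0317% and 0.0777%.

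miRNA strands from 1 hairpin had different log2 ratios. Over 19 paired strands the median absolute difference was 1.61 (interval 0.382 to 3.25), 12 pairs differed by over 1, and the widest, miR-989 and its partner, differed by 6.68, with only 262 reads for the partner. A change in the abundance of hairpins alone would give both strands of a single hairpin 1 ratio, unlike the 12 pairs that differed by over 1. For the pairs as a set it stays open, since the interval runs down to 0.382, a small difference. Families counted together, such as miR-2, can pool several hairpins, and some partners had few reads. Isoforms that differ at the 3' end differed by a median of 0.623 (interval 0.509 to 0.753) over 221 comparisons, and isoforms that differ at the 5' end by 0.465 (interval 0.318 to 1.06) over 32. Neither interval settles whether a ligation bias is set by that end, so such biases cannot be told apart from other sources; strand selection or stability in the mutant also stays open, untested. The strand differences, the unequal substitution neighbours (27.1% against 6.45%) and the lower ratios of longer miRNA reads leave open a technical difference between libraries. Such a difference could affect the piRNA to miRNA ratio and the single miRNA ratios.

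The higher 10-nt overlap share of the homozygote (20.7% against 8.53%) was set against fewer reads and against leftover structural RNA. Heterozygous reads thinned to the homozygous number, in each segment where that number was lower, reached 10.4% (10.2% to 10.5% over 20 draws). Segments with more homozygous reads were not thinned, so a shift of reads toward them was not tested. Over segments read from both strands the homozygous share was higher by 0.135 as a fraction. Only opposite-strand pairs count, so 1-sided fragments could hardly raise the share in any segment, and this comparison cannot weigh them. The log2 ratio of 10-nt pairs above background exceeded that of reads by 1.64, but the higher share itself fixes that sign, so this value decides nothing. Heterozygous 5' ends with a partner at 10 nt only had a log2 ratio higher by 1.06 than those with a partner at 9 or 11 nt only. The 95% interval over 1000 resamplings of segments was 0.377 to 1.76. At equal heterozygous reads per 5' end the difference was 1.29 (0.129 to 2.81). These ends are classed from the same pairs that give the overlap shares. A higher 10-nt share in the homozygote by itself favours such differences, so they are not independent support. A candidate explanation, found on the same 2 libraries and without an independent test, is that ping-pong piRNAs depend less on Minotaur than primary piRNAs do. However, A at position 10 was divided among reads that do not begin with U. The shares were 44.6% of heterozygous and 39.1% of homozygous repeat reads, and 32.8% and 32.4% of gene reads. Gene reads with 1 position had 28.7% and 22.9%, those with several positions 33.8% and 45.5%, and unannotated reads 36.7% and 44.4%. Sequence-dependent library differences were not tested there.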

How the results depend on the processing

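No paired analysis was possible because each genotype has 1 library. The alternatives fixed beforehand for the transposon lists, the count of families and both clusters were not run, since the files give no element names or positions. Alternatives other than 24 to 27 nt and distinct sequences for the piRNA ratio and the overlap shares, and other than the median miRNA and the whole file for the follicle-cell miRNAs, were chosen after seeing the data. The cause of each shift was not tested, except that fewer segments pass a higher minimum. The log2 ratio of piRNA-sized to miRNA reads (-1.51) kept its sign at 24 to 27 nt (-1.75), with distinct sequences (-1.59), for reads beginning with U (-1.93), with unmapped reads (-1.46), with miR-989 left out of the unit (-1.09), with the median miRNA set to 0 (-2.11), per 1000000 reads of the file (-1.89) and per 1000000 21-nt reads (-3.35). With structural segments kept it was 0.13, which reverses it. The 10-nt overlap share stayed higher in the homozygote at 24 to 27 nt (7.96% against 22.8%), with distinct sequences (5.28% against 7.33%) and over segments read from both strands (9.57% against 23.1%). The number of lower segments was 148 and of higher segments 22 at a minimum of 1000 reads. Higher segments numbered 97 for reads beginning with U and 30 with distinct sequences. Elsewhere lower segments numbered from 1124 to 1417 and higher ones from 112 to 187. For segments read from 1 strand the median was -3.64 per 1000000 reads of the file, -2.84 with miR-989 left out of the unit, -1.76 at a minimum of 1000 reads, -3.48 for reads beginning with U, -2.55 with structural segments kept and -1.53 with distinct sequences. For segments read from both strands it was -0.72 at that minimum and -1.45 with distinct sequences, and within its interval otherwise. The follicle-cell miRNA median was -1.02 relative to the median miRNA and -0.80 per 1000000 reads of the file. It was -1.03 with miR-989 left out of the list and -0.000285 with miR-989 left out of the unit. In that last setting the median was that of miR-318, with miR-989 at 5.27 and miR-994 at -1.22. Of 123 further values for single miRNAs and read classes under 3 other units, 9 changed sign, all for values within 2-fold. Counting intervals are narrow for the read classes and wide for rare miRNAs, such as miR-309 (2.44 to 10.34), miR-4 (2.59 to 7.59) and miR-124 (-1.19 to 1.23), and no value has a replicate.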

Other observations

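Fragments of the individual structural RNAs differed unequally. Per 1000000 miRNA reads, the segment of 2S rRNA had 81429 reads in the heterozygote and 303335 in the homozygote (log2 1.90). That of 5S rRNA was at 4173 and 128626 (log2 4.95), and that of 18S rRNA at 3284 and 27534 (log2 3.07). 5.8S rRNA (log2 0.69) and tRNA-Asp (log2 0.45) differed by less than 2-fold.

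Reads of 21 nt, the length of Drosophila siRNAs, formed a separate peak among mapped reads outside miRNAs and structural segments. They numbered 126016 per 1000000 miRNA reads in the heterozygote and 452591 in the homozygote, and the ratio was alike for repeat (log2 1.78) and gene reads (log2 1.94). Of these reads 51.6% began with U in the heterozygote and 39.9% in the homozygote. Opposite-strand 21-nt reads on segments overlapped by 19 nt, as strands of a Dicer duplex do, in 6.86% and 7.35% of pairs, below the highest share at another overlap in each library (7.60% and 7.61%). Repeat reads of 18 nt, too short to be placed on segments and below the selected size, were at 51150 and 303806.

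Unannotated piRNA-sized reads with several genome positions had the greatest fold difference of the classes split by positions, at 7.95-fold lower in the homozygote, with 5466 and 859 reads. The sequences seen in both libraries numbered 321934 and carried 57.8% of heterozygous and 77.6% of homozygous reads.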
